A study of Mus musculus with 8 samples.

How the data were processed

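Total RNA of mouse liver was measured on 8 single-colour oligonucleotide arrays: 2 of normal diet liver, and 3 each of non-tumour and tumour tissue from livers of mice on high fat diet. Per the labels, all mice had received DMBA as neonates, and amplified aminoallyl RNA was coupled to Cy5. Tumour and non-tumour arrays with the same mouse number (117, 186 and 1) come from the same liver per the labels. The number 117 also appears on normal diet, where it cannot be the same animal and pairs nothing.

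The deposited normalized intensity of a probe is, as recomputed from the scanner files, the spot median minus the mean of the array's blank spots, divided by 1 factor per array that sets the median of the listed probes to 25 (r2 = 1 on every array). In the deposited tables probes near the blank level have no value: the dimmest listed probe of an array lay 1.25 to 1.57 standard deviations above the blank mean, and 1 brighter probe on each of 2 arrays (normal diet 120, tumour 1) has no value either. Of the probes 81.8% to 88.5% were listed per array. Deposited intensities are used for the levels in the text and as an alternative in the tests. They were treated as linear values.

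For the tests the scanner spot medians were used. Of 27456 spots, 3982 control, blank and no-probe spots were left out, and the other 23474 held 23473 probes, 1 of them on 2 spots, of which the first was used. Of 23473 probes 20690 had 1 gene symbol and 2783 had none in the array table, and symbols were compared with the GRCm38.p6 annotation by gene number (20556 probes) or accession (19076 probes), which disagreed for 9 and changed 0 symbols. These gave 19321 genes, of which 1283 had more than 1 probe, and the probe with the highest mean signal was kept. A gene was tested if it was listed on all arrays of at least 1 group, which left out 2521 and kept 16800, of which 15339 were listed on all 8 arrays.

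Signals were corrected by normexp with the blank spots as negative controls and an offset of 50, quantile normalized and taken to log2 with limma 3.58.1 in R 4.3.3. The design fixed beforehand named normexp with that offset without naming the background source. The local background reading followed the signal of its own spot (rank correlation 0.913 to 0.959, median 48.7% of the spot signal in probes above 1000, and above the spot itself in 34 to 423 probes per array), so blank spots were used, a choice made after the files were seen and before any fit. Normexp with the local background was added as an alternative after seeing the data.

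Group means were fitted to all 8 arrays with limma and moderated by empirical Bayes (5 residual and 1.49 prior degrees of freedom), and the 3 pairwise differences were tested 2-sided with Benjamini-Hochberg adjustment over all genes. A gene changed where its adjusted p was below 0.05. Mouse number stayed out of the main model and entered an alternative as a fixed block of the 6 high fat diet arrays. Deviations from the group means of tumour and non-tumour tissue correlated at 0.443, 0.148 and 0.167 for the same mouse (117, 186, 1) and at -0.275 to 0.028 for different mice. Deviations cancel out within a group, so higher values for the same mouse bring lower ones for different mice. Array correlations were 0.984 to 0.996 within groups and 0.919 to 0.983 between them.

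The design, the alternatives, 38 gene lists and 13 genes were fixed before the data were examined. The lists held 946 names, of which 859 were on the array and 827 were measured. Some genes stand on several lists, such as C8b on the male-biased and complement lists. Calls on lists that share members are therefore not independent results. They were tested 2-sided with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and members were also adjusted over the list alone. Genes named in the text come from the 6 largest rises and falls per comparison that passed, were listed on every array of both groups and did not overlap, from up to 4 called members per list by size of change, and from the 13 genes fixed beforehand, and the text takes a part of the first 2 kinds. Genes in the other observations were chosen after their values were seen.

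The model fit and the calling of genes were tested on simulated log2 values with 200 changed genes and independent noise per gene. Background correction, normalization, probe choice and filter were not part of this test. Changes were added after the offset, so the recovery below does not cover the understated folds of dim genes. Changes of 0.5, 1 and 2 log2 units were recovered in 73.1%, 95.5% and 100% of genes between tumour and non-tumour tissue, 70.1%, 91.0% and 97.0% between diets, and 71.6%, 95.5% and 98.5% between tumours and normal diet liver. Unchanged genes were called in 0.0663%, 0.0843% and 0.0663% of cases, rates that hold for independent noise without batch or pairing.

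Alternatives were blank-subtracted signal, scaling to the same median, the authors' values, no filter or a stricter one, the mean of probes, an intensity trend, the compared groups alone, a mouse block, the removal of each array, and other set tests. Where a single normal diet array was left, its spread was assumed to be that of the other groups. Plots were drawn with matplotlib 3.10.9.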

Results

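Gene expression was compared in livers of mice that had received the carcinogen DMBA as neonates and then 30 weeks of normal diet (2 livers) or high fat diet (tumour and non-tumour tissue of 3 livers). Levels are means ± SD of the deposited normalized intensity, on which the median of the listed probes of each array is 25. Log2 fold changes are given ± SE with adjusted p values from limma, and arrays are named by group and mouse number. All 3 comparisons share arrays, and the folds of dim genes are understated because a fixed offset was added to every signal.

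Tumour tissue of high fat diet-fed mice carried far higher levels of several transcripts than the surrounding liver (n = 3 arrays each). Tspan8, which encodes a tetraspanin of epithelial cell membranes, rose from 35.2 ± 26.2 to 3502 ± 1378 (log2 fold change 5.65 ± 0.35, adjusted p 0.000362). Akr1c18, a steroid-reducing aldo-keto reductase, rose from 70.6 ± 54.4 to 4011 ± 1030 (5.43 ± 0.33, adjusted p 0.000362). Spink1, a trypsin inhibitor, rose from 24.9 ± 12.9 to 2084 ± 622 (5.09 ± 0.23, adjusted p 0.000155). Igfbp1, an insulin-like growth factor binding protein, rose from 283 ± 113 to 6476 ± 2668 (4.59 ± 0.57, adjusted p 0.00240). Among the deepest falls were Oat, the ornithine aminotransferase of pericentral hepatocytes (3036 ± 901 to 261 ± 189, -3.33 ± 0.51, adjusted p 0.00501), the periportal cytochrome P450 gene Cyp2f2 (2910 ± 751 to 288 ± 230, -3.26 ± 0.63, adjusted p 0.0116) and the liver-derived growth factor gene Igf1 (2409 ± 78.1 to 287 ± 144, -2.86 ± 0.39, adjusted p 0.00350). A probe that the array table assigns to the pituitary hormone gene Fshb was bright in non-tumour liver and fell in tumours (1742 ± 832 to 158 ± 134, -3.11 ± 0.65, adjusted p 0.0153). That call ended with mouse as a block (adjusted p 0.0543) and without non-tumour array 117 (0.0539) or 1 (0.0549), in a range of 0.00262 to 0.168 over its alternatives.

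Liver tumour and oncofetal markers rose as a list: 19 of 29 measured members rose, 21 adjusted over the list alone (adjusted p = 1.2e-12, and adjusted p = 0.0730 with an estimated correlation). The fetal plasma protein gene Afp went from 6.60 ± 0.954 to 864 ± 390 (4.24 ± 0.23, adjusted p 0.000271). The oncofetal proteoglycan gene Gpc3 went from 12.1 ± 4.28 to 729 ± 91.3 (3.98 ± 0.13, adjusted p 5.1e-05). The stearoyl-CoA desaturase gene Scd2 went from 30.3 ± 10.8 to 999 ± 231 (4.00 ± 0.13, adjusted p 5.5e-05). Cholesterol synthesis genes rose in 17 of 19 cases, 17 adjusted over the list alone (adjusted p = 8.5e-10, and adjusted p = 0.257 with an estimated correlation). Sqle, the squalene epoxidase, was at 60.6 ± 17.5 and 1135 ± 88.5 (3.70 ± 0.38). Cyp51, the lanosterol demethylase, was at 164 ± 28.9 and 893 ± 213 (2.38 ± 0.24). In the unfolded protein and integrated stress response list 19 of 26 members rose and 1 fell, 21 and 1 adjusted over the list alone (adjusted p = 1.6e-10), a call that held at adjusted p = 0.0497 with an estimated correlation. Its members include the endoplasmic reticulum chaperone gene Hspa5 (3626 ± 369 to 7988 ± 848), the serine synthesis gene Psat1 (14.7 ± 1.42 to 369 ± 181) and asparagine synthetase, Asns (6.90 ± 0.656 to 170 ± 113). Of 26 ribosomal protein genes 20 rose and 1 fell, 22 and 1 adjusted over the list alone (adjusted p = 9.3e-09, and adjusted p = 0.383 with an estimated correlation). Rpl3 rose by a log2 fold change of 0.87 ± 0.13 and Rpl5 by 0.86 ± 0.14, while Rps19 fell by 0.83 (SE 0.06).

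Lists of senescence, cell cycle and growth signalling genes were called higher in tumours as well. The senescence and secretory phenotype list was called with 9 of 28 members up, 9 adjusted over the list alone (adjusted p = 0.000761, and adjusted p = 0.383 with an estimated correlation). Cdkn2b, a cyclin-dependent kinase inhibitor, rose from 9.43 ± 1.33 to 556 ± 201 (3.57 ± 0.19, adjusted p 0.000271). The alarmin gene Il33 rose from 16.6 ± 2.39 to 76.6 ± 24.2 (1.00 ± 0.13, adjusted p 0.00325). The chemokine gene Cxcl1 rose from 126 ± 49.1 to 741 ± 479 (2.24 ± 0.45, adjusted p 0.0139). The kinase inhibitor gene Cdkn1a rose from 37.7 ± 9.36 to 120 ± 68.1 (0.98 ± 0.26, adjusted p 0.0377). The call on Cxcl1 ended without non-tumour array 117 (adjusted p 0.05005, in a range of 0.00229 to 0.850 over its alternatives). That on Cdkn1a ended with mouse as a block (0.0638) and without normal diet array 117 (0.0696) or 120 (0.0709), non-tumour array 117 (0.112), 186 (0.0882) or 1 (0.0799), or tumour array 117 (0.0786), and with the compared groups alone (0.0683), in a range of 0.00987 to 0.492. With no filter the call on Cdkn1a ended as well. Cell cycle genes rose in 7 of 32 cases and fell in 1, 12 and 1 adjusted over the list alone (adjusted p = 0.00306, and adjusted p = 0.560 with an estimated correlation). Cyclin D1, Ccnd1, rose from 62.0 ± 6.38 to 174 ± 30.8 and cyclin E1, Ccne1, from 10.9 ± 4.42 to 47.5 ± 11.2. The proliferation marker Mki67 rose from 16.3 ± 2.41 to 32.4 ± 8.30 (0.33 ± 0.06, adjusted p 0.0116). RAS and MAPK feedback targets rose in 8 of 20 cases and fell in 1, 9 and 1 adjusted over the list alone (adjusted p = 0.0112, adjusted p = 0.519 with an estimated correlation, 0.0505 without non-tumour array 117, in a range of 0.00162 to 0.519). The MAPK phosphatase gene Dusp5, among them, was at 3.57 ± 0.971 and 66.8 ± 28.7. Immediate early genes were called higher with 3 of 20 up, 2 adjusted over the list alone, Egr1 among them (116 ± 78.3 to 567 ± 317, 2.04 ± 0.58, adjusted p 0.0458). The list's adjusted p = 0.0383 became adjusted p = 0.519 with an estimated correlation, and 0.126, 0.130 and 0.0634 without non-tumour array 117, tumour array 186 and non-tumour array 1 (range 0.00443 to 0.519). Egr1 itself lost its call without normal diet array 117 (0.0553) or 120 (0.0564), non-tumour array 117 (0.129) or 1 (0.133), or tumour array 186 (0.112) or 1 (0.120), with no filter (0.0602) and with the compared groups alone (0.0535), in a range of 0.0122 to 0.786.

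Lists of hepatocyte metabolism were called lower in the tumours. In the oxidative phosphorylation list 23 of 32 genes fell, 27 adjusted over the list alone (adjusted p = 5.1e-12), a call that held at adjusted p = 0.0497 with an estimated correlation. The succinate dehydrogenase subunit gene Sdhb was at 1570 ± 167 and 695 ± 54.5 and the cytochrome c oxidase subunit gene Cox5b at 3029 ± 192 and 1433 ± 140. PPAR alpha targets and fatty acid oxidation genes fell in 21 of 27 cases, 21 adjusted over the list alone where 1 also rose (adjusted p = 2.3e-07, and adjusted p = 0.383 with an estimated correlation). The fatty acid hydroxylase genes Cyp4a14 (3319 ± 631 to 352 ± 252) and Cyp4a10 (1675 ± 127 to 266 ± 112) and the peroxisomal thiolase gene Acaa1b (28594 ± 2798 to 7677 ± 2164) were among them. Wnt and pericentral genes fell in 18 of 22 cases and rose in 1, 18 and 2 adjusted over the list alone (adjusted p = 4.1e-06, and adjusted p = 0.460 with an estimated correlation). Examples were the bile acid and drug uptake carrier gene Slco1b2 (1940 ± 171 to 240 ± 149), Cyp1a2 (971 ± 312 to 128 ± 95.2) and glutamine synthetase, Glul (899 ± 213 to 155 ± 136, -2.27 ± 0.48, adjusted p 0.0164). Bile acid synthesis and transport genes fell in 18 of 29 cases and rose in 2, with the same counts adjusted over the list alone (adjusted p = 6.4e-06, and adjusted p = 0.383 with an estimated correlation). Among them were the sterol hydroxylase gene Cyp8b1 (1060 ± 104 to 123 ± 66.3), the bile acid uptake carrier gene Slc10a1 (1744 ± 66.3 to 326 ± 150) and Cyp7a1, which encodes the rate-limiting enzyme of bile acid synthesis (138 ± 28.7 to 25.4 ± 12.4, -1.36 ± 0.15, adjusted p 0.00177). Mature hepatocyte genes fell in 12 of 24 cases and rose in 2, 13 and 3 adjusted over the list alone (adjusted p = 0.00272, and adjusted p = 0.519 with an estimated correlation). The tyrosine breakdown gene Hpd was at 6022 ± 1029 and 651 ± 444 and glucose-6-phosphatase, G6pc, at 2634 ± 412 and 483 ± 240. With mouse as a block the adjusted p of Cyp4a14, Hpd, Cyp1a2 and Glul was 0.0584, 0.0614, 0.0615 and 0.0722, in ranges of 0.00104 to 0.161, 0.000737 to 0.191, 0.00148 to 0.130 and 0.00194 to 0.383 over their alternatives. With non-tumour array 117 left out that of Hpd, G6pc and Glul was 0.0512, 0.0541 and 0.0567 (range for G6pc 0.00243 to 0.0932). With non-tumour array 1 left out that of Hpd and Glul was 0.0560 and 0.0543. With tumour array 117 left out that of Glul was 0.0549.

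The lists of NRF2, xenobiotic receptor, male-biased and periportal genes were called lower as well, with fewer than 50% of their members falling. NRF2 and glutathione genes fell in 11 of 24 cases and rose in 1, 13 and 2 adjusted over the list alone (adjusted p = 0.00358, and adjusted p = 0.519 with an estimated correlation). Examples were the carboxylesterase gene Ces1g (965 ± 129 to 159 ± 53.9) and the aldehyde oxidase gene Aox1 (784 ± 81.5 to 206 ± 36.7). Aryl hydrocarbon and xenobiotic receptor targets fell in 10 of 21 cases and rose in 2, 11 and 2 adjusted over the list alone (adjusted p = 0.0112, and adjusted p = 0.519 with an estimated correlation). An example was Cyp2c37 (541 ± 121 to 82.3 ± 63.8, adjusted p 0.0112, 0.0583 with mouse as a block, in a range of 0.00177 to 0.953). Male-biased liver genes fell in 8 of 18 cases and rose in 1, 8 and 2 adjusted over the list alone (adjusted p = 0.00604, and adjusted p = 0.460 with an estimated correlation). The fatty acid elongase gene Elovl3 was at 640 ± 432 and 37.7 ± 20.7. Periportal genes fell in 9 of 20 cases and rose in 4, 11 and 5 adjusted over the list alone. The periportal adjusted p = 0.0430 became adjusted p = 0.519 with an estimated correlation, 0.0623 with mouse as a block, and 0.0587, 0.0577, 0.0711 and 0.0503 without normal diet array 117 or 120 or non-tumour array 117 or 186. With the compared groups alone it was 0.0586 (range 0.00352 to 0.519).

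Lists of markers of other liver cells were called in both directions. Endothelial markers rose in 6 of 22 cases and fell in 1, 7 and 1 adjusted over the list alone (adjusted p = 0.0282, adjusted p = 0.519 with an estimated correlation, 0.204 without tumour array 186, range 0.00143 to 0.519). Examples were Pecam1 (27.3 ± 1.73 to 63.4 ± 18.9) and Cd34 (9.60 ± 3.12 to 46.9 ± 12.7). Stellate cell and fibrosis genes rose in 8 of 32 cases and fell in 1, 9 and 3 adjusted over the list alone. The intermediate filament gene Vim was at 199 ± 43.6 and 453 ± 54.7 and the matrix protein gene Sparc at 243 ± 24.1 and 542 ± 65.6. The stellate adjusted p = 0.0430 became adjusted p = 0.560 with an estimated correlation, 0.0578 with mouse as a block, and 0.0587, 0.0551, 0.252 and 0.127 without normal diet array 117 or 120, tumour array 186 or non-tumour array 1. It was 0.0651 with genes listed on all 8 arrays and 0.0586 with the compared groups alone (range 0.00636 to 0.560). Cholangiocyte markers rose in 4 of 16 cases and fell in 1, with the same counts adjusted over the list alone, Tspan8 and the keratin gene Krt23 (114 ± 36.8 to 382 ± 126) among them. Their adjusted p = 0.0430 became adjusted p = 0.519 with an estimated correlation and 0.0575, 0.0551, 0.189, 0.101 and 0.0634 without normal diet array 117 or 120, tumour array 117 or non-tumour array 186 or 1. With the compared groups alone it was 0.0582 (range 0.0145 to 0.519). Red blood cell markers fell in 3 of 8 cases, 3 adjusted over the list alone (adjusted p = 0.0326, adjusted p = 0.519 with an estimated correlation, 0.276 without non-tumour array 117 and 0.102 without tumour array 186, range 0.00515 to 0.519). Examples were Alas2 (324 ± 34.9 to 108 ± 6.68) and Car1 (34.0 ± 2.97 to 4.90 ± 2.26). Macrophage and Kupffer cell markers were not called as a list (adjusted p 0.648), but 4 of 29 rose and 4 fell. Cd14 was at 47.7 ± 17.1 and 329 ± 131, Cd9 at 231 ± 36.1 and 845 ± 215, and the Kupffer cell lectin gene Clec4f at 283 ± 98.6 and 71.3 ± 24.9 (Clec4f adjusted p 0.00801, 0.0632 with mouse as a block, in a range of 0.00124 to 0.417).

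Other lists were not called between tumour and non-tumour tissue, some of them with strong members. They were acute phase response (14 of 29 rose and 10 fell, adjusted p 0.440), complement and coagulation (9 of 27 rose and 5 fell, 0.250), fatty acid synthesis (8 of 20 rose and 5 fell, 0.478), female-biased liver genes (7 of 20 rose and 6 fell, 0.592) and lipid droplet and fat storage (4 of 27 rose and 7 fell, 0.101). The lipid droplet list was called lower with the authors' values (0.0205) and with the local background of each spot (0.0297, in a range of 0.0128 to 0.519). The set test pointed up for acute phase, muscle, neutrophil and pancreas lists although their medians were negative, and the female-biased list had a median of 0.06 and a mean of -0.08. Within them the acute phase and tumour marker gene Lcn2 rose from 400 ± 103 to 4987 ± 1783 (3.73 ± 0.25, adjusted p 0.000452). The lipase gene Pnpla5 rose from 20.5 ± 14.3 to 398 ± 102 (2.89 ± 0.23, adjusted p 0.000675), and the lipid droplet gene Cidea fell from 1737 ± 268 to 363 ± 149 (adjusted p 0.0141). The adjusted p was 0.371 for adipose tissue markers, 0.419 for B and plasma cell markers and 0.648 for circadian clock genes. It was 0.490 for glycolysis and for the interferon response, 0.478 for the prostaglandin pathway, 0.926 for neutrophil markers, 0.810 for T and NK cell markers and 0.648 for sex chromosome genes. Muscle and mesothelial markers (0.619) and pancreas and gut markers (0.608) were not called either, although the mesothelial gene Msln (140 ± 10.8 to 531 ± 73.5) and the elastase gene Cela1 (103 ± 10.5 to 413 ± 124) rose. Prostaglandin synthase Ptgs2 was at 7.80 ± 0.520 and 8.47 ± 1.61 (log2 fold change 0.02 ± 0.03, adjusted p 0.734). The cytokine gene Il1b was at 45.4 ± 16.4 and 54.2 ± 8.16 (0.17 ± 0.14, 0.474). The smooth muscle actin gene Acta2 was at 79.9 ± 84.8 and 176 ± 120 (0.99 ± 0.56, 0.262). The collagen gene Col1a1 was at 12.7 ± 2.22 and 26.3 ± 17.1 (0.28 ± 0.14, 0.196). The chemokine gene Cxcl9 was at 164 ± 87.4 and 241 ± 20.8 (0.68 ± 0.29, adjusted p 0.146, and 0.0126 without non-tumour array 186, in a range of 0.0126 to 0.592 over its alternatives).

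Of 16800 genes tested between tumour and non-tumour tissue, 4267 changed (2008 higher, 2259 lower), 287 and 282 of them over 2-fold, and 21 of 38 lists were called (11 higher, 10 lower). Of these 21 lists 2 held with an estimated correlation, the oxidative phosphorylation and unfolded protein response lists. With scaling to the same median 1572 genes were higher and 2641 lower (37.3% higher against 47.1%), and with the authors' values 1541 and 2253 (40.6%). With mouse as a block 3485 genes changed (1642 higher, 1843 lower), 2988 of which were also called without the block, and 19 lists were called. In 6953 genes (41.4%, where chance gives 10%) no tumour array overlapped a non-tumour array. With the local background of each spot in place of the blank spots, a setting chosen after seeing the data, 136 genes changed (103 higher, 33 lower, so 75.7% higher) and 15 lists were called. Endothelial (adjusted p 0.0993), immediate early (0.181), MAPK (0.145), red blood cell (0.243), ribosomal (0.0653), senescence (0.0676) and stellate (0.304) lists lost their calls there, as did 46 of the 60 named genes called here, while 91.7% of the 4267 genes kept their direction. By fry 23 lists were called, with cell cycle (0.0650), endothelial (0.0511), immediate early (0.0975) and stellate genes (0.106) not among them. It called fatty acid synthesis (0.0106), female-biased (0.0302) and muscle (0.0105) lists higher, and adipose (0.0455), lipid droplet (0.0128) and prostaglandin (0.0373) lists lower.

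**Figure D1:**
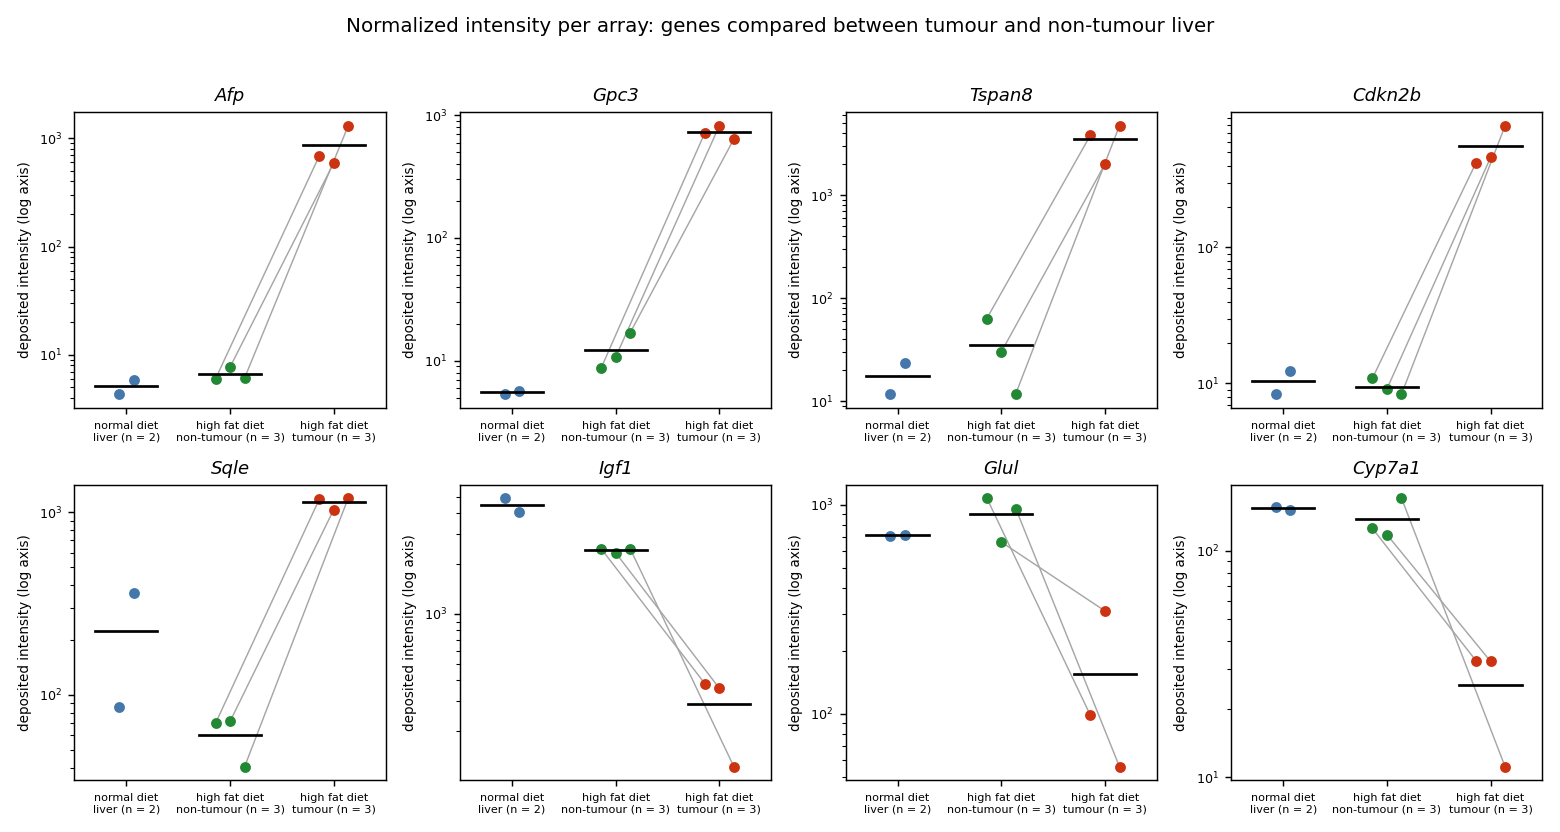
Deposited normalized intensity of 8 genes on a log axis. Each point is an array (2 of normal diet liver, 3 of high fat diet non-tumour liver, 3 of high fat diet tumour), black bars are group means and grey lines join tumour and non-tumour tissue of the same mouse. Afp, Gpc3, Tspan8, Cdkn2b and Sqle were higher, and Igf1, Glul and Cyp7a1 lower, in tumour than in non-tumour tissue.

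Non-tumour liver of mice on high fat diet (n = 3) was set against liver on normal diet (n = 2), where Apoa4 rose and Hsd3b5 fell most among the named genes. The slope between readings at different scanner gains was 0.216 on normal diet arrays and 0.232 to 0.235 on high fat diet arrays, and blank spots had means of 18.4 to 18.5 and 20.5 to 22.7. An array or scan batch therefore cannot be told apart from diet in any comparison with normal diet. Apoa4, an apolipoprotein of triglyceride-rich particles, rose from 408 ± 83.3 to 19768 ± 3871 (log2 fold change 5.59 ± 0.24, adjusted p 0.000894). Ly6d, a membrane-anchored lymphocyte antigen gene, rose from 25.4 ± 1.98 to 1593 ± 287 (4.48 ± 0.23, adjusted p 0.00105). Cidea, which promotes lipid droplet growth, rose from 58.6 ± 55.0 to 1737 ± 268 (adjusted p 0.00892). Ifi27l2b rose from 110 ± 21.2 to 930 ± 85.2 (2.67 ± 0.15, adjusted p 0.00127). A probe without an accession that is named for the kinase gene Prkcq rose from 24.9 ± 0.495 to 779 ± 162 (3.47 ± 0.16, adjusted p 0.00105), where another Prkcq probe gave -0.02. Hsd3b5, a steroid dehydrogenase of male liver, fell from 3453 ± 423 to 7.33 ± 3.63 (-5.74 ± 0.08, adjusted p 2.3e-06). A probe without an accession named for the tumour suppressor gene Apc fell from 561 ± 150 to 41.4 ± 11.1 (-2.59 ± 0.17, adjusted p 0.00189). The fall of Hsd3b5 reversed to 0.43 (adjusted p 0.196, in a range of 2.4e-09 to 0.196) with the local background of each spot, which read 3204 and 2545 around spots of 3143 and 2459 on the normal diet arrays. The call on Cidea ended without normal diet array 120 (adjusted p 0.0681, in a range of 0.000524 to 0.0807).

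Lipid droplet and fat storage genes rose in 11 of 27 cases, 15 adjusted over the list alone (adjusted p = 1.4e-12, and adjusted p = 0.167 with an estimated correlation). Besides Apoa4 and Cidea they included the fatty acid transporter gene Cd36 (391 ± 116 to 1926 ± 112, 2.33 ± 0.31, adjusted p 0.0168) and the droplet protein gene Cidec (40.4 ± 0.141 to 354 ± 42.3, 2.20 ± 0.28, adjusted p 0.0147). PPAR alpha targets and fatty acid oxidation genes rose in 4 of 27 cases, 10 adjusted over the list alone (adjusted p = 1.6e-07, and adjusted p = 0.234 with an estimated correlation). The pantetheinase gene Vnn1 was at 362 ± 22.2 and 1356 ± 201 (1.90 ± 0.32, adjusted p 0.0323). The acyl-CoA dehydrogenase gene Acadl was at 1114 ± 37.1 and 1379 ± 32.7 (0.49 ± 0.03, adjusted p 0.00119). Fatty acid synthesis genes rose in 3 of 20 cases and fell in 1, 6 and 1 adjusted over the list alone (adjusted p = 0.00600, and adjusted p = 0.234 with an estimated correlation). With the authors' values the list median flipped from 0.22 to -0.01, while camera still called the list higher (adjusted p 0.0156). The desaturase gene Fads2 (248 ± 20.6 to 791 ± 36.1) and the elongase gene Elovl5 (4358 ± 1116 to 9514 ± 1581) rose, and the acetyl-CoA synthetase gene Acss2 (712 ± 103 to 256 ± 37.3) fell. Adipose tissue markers rose in 3 of 10 cases, 4 adjusted over the list alone (adjusted p = 0.00588, and adjusted p = 0.234 with an estimated correlation). An example was the adipogenic receptor gene Pparg (130 ± 15.9 to 262 ± 33.6). Pparg and Cidec, which both rose, stand on the adipose and the lipid droplet list alike. The call on the adipose list ended with scaling to the same median (adjusted p 0.0656, in a range of 0.00293 to 0.234). Glycolysis genes rose in 4 of 22 cases, 5 adjusted over the list alone. Hexokinase Hk2 was at 7.35 ± 1.48 and 87.3 ± 15.2. The glycolysis adjusted p = 0.0207 became adjusted p = 0.572 with an estimated correlation, 0.0608 with scaling to the same median and 0.0970 without normal diet array 117 (range 0.00555 to 0.572).

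Of the 42 named genes called between diets 29 lost the call in at least 1 fit with an array left out, while the log2 fold changes of all 42 stayed at 0.75 to 1.26 times their values on 8 arrays. Leaving out either normal diet array left a group of 1. With normal diet array 117 left out the adjusted p of Cd36, Cidec, Vnn1, Elovl5, Acss2, Pparg and Hk2 was 0.0677, 0.103, 0.172, 0.0578, 0.0635, 0.0829 and 0.0916. With normal diet array 120 left out it was 0.121, 0.104, 0.178, 0.134, 0.121, 0.0536 and 0.102. With non-tumour array 117 left out that of Cd36, Cidec, Vnn1, Elovl5, Acss2 and Hk2 was 0.0553, 0.0543, 0.0737, 0.0750, 0.0542 and 0.0508. With non-tumour array 186 left out that of Cd36, Cidec, Vnn1 and Elovl5 was 0.0600, 0.0542, 0.0918 and 0.0736. Vnn1 was at 0.0779 without non-tumour array 1 and 0.0587 without tumour array 117, Acss2 at 0.0514 without non-tumour array 1, and Acadl at 0.251 with the authors' values. Elovl5 was at 0.0517 with the compared groups alone. Over all alternatives the ranges were 0.00202 to 0.999 for Cd36, 0.00144 to 0.384 for Cidec, 0.00641 to 0.999 for Vnn1 and Elovl5, 0.00102 to 0.999 for Acadl, 0.00460 to 0.999 for Acss2, 0.00331 to 0.505 for Pparg and 0.000972 to 0.563 for Hk2.

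Male-biased liver genes were called lower and female-biased ones higher as lists. Male-biased liver genes fell in 8 of 18 cases, 11 adjusted over the list alone (adjusted p = 1.5e-10, and adjusted p = 0.171 with an estimated correlation). Beside Hsd3b5 these included the organic anion carrier gene Slco1a1 (1339 ± 146 to 52.9 ± 25.4, -3.55 ± 0.29, adjusted p 0.00367) and the complement component gene C8b (931 ± 19 to 113 ± 17.3, -2.39 ± 0.14, adjusted p 0.00137). The hydroxylase genes Cyp4a12a (1634 ± 313 to 213 ± 108, -2.50 ± 0.37, adjusted p 0.0217) and Cyp4a12b (706 ± 146 to 94.5 ± 28.7, -2.22 ± 0.21, adjusted p 0.00575) fell as well. Female-biased liver genes rose in 6 of 20 cases, 8 adjusted over the list alone where 3 fell (adjusted p = 0.00600, adjusted p = 0.203 with an estimated correlation, 0.0656 with scaling to the same median, range 0.000347 to 0.203). Cyp2b9 rose from 11.8 ± 7.21 to 733 ± 179 (3.70 ± 0.18, adjusted p 0.00105). Cyp2b10 rose from 62.3 ± 32.0 to 385 ± 65.2 (2.03 ± 0.18, adjusted p 0.00495). The steroid hydroxylase gene Cyp17a1 rose from 22.7 ± 0.566 to 197 ± 31.0 (1.82 ± 0.23, adjusted p 0.0146). The call on Cyp4a12a ended without normal diet array 117 (0.105) or 120 (0.150) or non-tumour array 186 (0.0677), that on Cyp4a12b without normal diet array 120 (0.0531), and that on Cyp17a1 without normal diet array 117 (0.101) or 120 (0.102) or non-tumour array 186 (0.0545). Their ranges over the alternatives were 0.00262 to 0.704, 0.000330 to 0.196 and 0.000544 to 0.102.

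Markers of macrophages, inflammation and matrix were called higher as lists in high fat diet liver. Macrophage and Kupffer cell markers rose in 3 of 29 cases, 16 adjusted over the list alone where 2 fell (adjusted p = 8.6e-07, and adjusted p = 0.234 with an estimated correlation). These were the lipid-associated macrophage receptor gene Trem2 (12.8 ± 0.778 to 55.3 ± 8.38, 0.81 ± 0.08, adjusted p 0.00651), Gpnmb (25.6 ± 2.97 to 75.8 ± 20.3, 0.78 ± 0.15, adjusted p 0.0436) and Cd5l (395 ± 80.8 to 728 ± 103, 0.94 ± 0.17, adjusted p 0.0393). Acute phase genes rose in 9 of 29 cases, 13 adjusted over the list alone where 2 fell (adjusted p = 6.9e-06, and adjusted p = 0.234 with an estimated correlation). Rises were seen for the serum amyloid genes Saa1 (1031 ± 380 to 4191 ± 970) and Saa2 (343 ± 117 to 1814 ± 140), Lcn2 (43.2 ± 7.42 to 400 ± 103) and Orm2 (67.9 ± 25.3 to 296 ± 56.8). Stellate cell and fibrosis genes rose in 3 of 32 cases, 8 adjusted over the list alone (adjusted p = 1.9e-06, and adjusted p = 0.234 with an estimated correlation). Col3a1 was at 106 ± 28.8 and 354 ± 53.6 and Sparc at 123 ± 13.6 and 243 ± 24.1. Liver tumour and oncofetal markers rose in 5 of 29 cases, 6 adjusted over the list alone (adjusted p = 1.9e-06, and adjusted p = 0.203 with an estimated correlation). Examples were Ly6d, Lcn2 and the calcium-binding protein gene S100a11 (61.1 ± 9.97 to 416 ± 66.9). NRF2 and glutathione genes rose in 5 of 24 cases, 13 adjusted over the list alone (adjusted p = 9.4e-07, and adjusted p = 0.234 with an estimated correlation). Sulfiredoxin, Srxn1, was at 309 ± 2.90 and 663 ± 122 and the glutathione transferase gene Mgst3 at 261 ± 9.33 and 520 ± 66.3. In the cell cycle list, called higher (adjusted p = 7.2e-06, and adjusted p = 0.477 with an estimated correlation), the replication helicase gene Mcm2 rose (16.4 ± 0.919 to 29.7 ± 2.74), 1 of 32 members, where 6 rose and 1 fell adjusted over the list alone.

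Calls on these single genes also ended in some fits with an array left out, at log2 fold changes of 0.73 to 1.15 for Cd5l, 1.43 to 1.81 for Orm2 and 2.10 to 2.43 for Lcn2. With normal diet array 117 left out the adjusted p of Trem2, Gpnmb, Cd5l, Lcn2, Orm2, Col3a1, Sparc, S100a11, Srxn1, Mgst3 and Mcm2 was 0.0550, 0.204, 0.204, 0.0862, 0.0578, 0.211, 0.172, 0.0609, 0.0862, 0.158 and 0.182. With normal diet array 120 left out it was 0.0594, 0.224, 0.0895, 0.102, 0.102, 0.129, 0.209, 0.0554, 0.0887, 0.132 and 0.179, with Saa1 at 0.0753. With non-tumour array 117 left out that of Gpnmb, Cd5l, Col3a1, Sparc and Mcm2 was 0.105, 0.103, 0.102, 0.107 and 0.0849. With non-tumour array 186 left out that of Gpnmb, Cd5l, Col3a1, Sparc, Mgst3 and Mcm2 was 0.0545, 0.108, 0.103, 0.106, 0.0677 and 0.0737. With non-tumour array 1 left out that of Col3a1, Sparc, Mgst3 and Mcm2 was 0.0564, 0.0525, 0.0659 and 0.0604. With tumour array 117 left out, which enters through the shared estimate of the spread, that of Gpnmb, Cd5l, Col3a1, Sparc and Mcm2 was 0.0781, 0.0689, 0.0669, 0.0682 and 0.0667. With tumour array 186 left out that of Gpnmb and Cd5l was 0.0610 and 0.0505. With tumour array 1 left out that of Cd5l was 0.0535. Over all alternatives the adjusted p reached 0.999 for Trem2, Gpnmb, Saa1, Col3a1, Sparc, Srxn1 and Mcm2, 0.204 for Cd5l, 0.452 for Lcn2, 0.102 for Orm2, 0.736 for S100a11 and 0.878 for Mgst3. Its lowest values for these 12 genes lay between 0.000541 and 0.0167. With no filter Gpnmb, Cd5l and Sparc were at 0.0577, 0.0519 and 0.0516, and with the compared groups alone Gpnmb and Cd5l were at 0.0741 and 0.0717. The second probe of Col3a1 gave a log2 fold change of 0.09 where the brighter one gave 1.45.

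A smaller set of lists was called lower in high fat diet non-tumour liver. Complement and coagulation genes fell in 6 of 27 cases, 10 adjusted over the list alone where 1 rose (adjusted p = 0.000510, adjusted p = 0.203 with an estimated correlation). The falls included the coagulation factor genes F11 (529 ± 32.5 to 183 ± 26.1, -1.15 ± 0.17, adjusted p 0.0205) and F7 (758 ± 106 to 364 ± 62.1, -0.79 ± 0.12, adjusted p 0.0217). Cholesterol synthesis genes fell in 3 of 19 cases, 6 adjusted over the list alone where 2 rose (adjusted p = 0.00289, adjusted p = 0.474 with an estimated correlation). The isomerase gene Idi1 was at 612 ± 219 and 157 ± 17.9 (adjusted p 0.0272). Nsdhl was at 406 ± 121 and 133 ± 16.7 (adjusted p 0.0393). Ribosomal protein genes were lower as a list at a median of -0.27 (adjusted p = 8.1e-05, adjusted p = 0.424 with an estimated correlation), although 1 of 26 fell and 1 rose, 4 and 1 adjusted over the list alone. Rpl4 fell by 0.34 (SE 0.06, adjusted p 0.0414) and Rps19 rose by 0.49 (SE 0.07, adjusted p 0.0172). With scaling to the same median none of these lists was called, at adjusted p 0.336 for complement and ribosomal genes and 0.167 for cholesterol synthesis (ranges 6.9e-06 to 0.336, 4.6e-06 to 0.834 and 4.2e-06 to 0.474). Cholesterol synthesis was at 0.100 without normal diet array 120.

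In the lists called lower, single genes likewise lost calls with an array left out, at log2 fold changes of -1.25 to -1.07 for F11, -1.82 to -1.13 for Idi1 and -1.42 to -0.84 for Nsdhl. With normal diet array 117 left out the adjusted p of F11, F7, Nsdhl, Rpl4 and Rps19 was 0.131, 0.138, 0.0578, 0.238 and 0.0916. With normal diet array 120 left out that of F11, F7, Idi1, Nsdhl, Rpl4 and Rps19 was 0.124, 0.0891, 0.123, 0.175, 0.142 and 0.124. With non-tumour array 117 left out that of F11, F7, Idi1, Nsdhl and Rpl4 was 0.0698, 0.0528, 0.0830, 0.107 and 0.0987. With non-tumour array 186 left out that of Idi1, Nsdhl and Rps19 was 0.0785, 0.0747 and 0.0509. With non-tumour array 1 left out that of F11, Idi1, Nsdhl and Rpl4 was 0.0550, 0.0638, 0.0941 and 0.0964. With tumour array 117 left out that of Nsdhl and Rpl4 was 0.0696 and 0.0685. With tumour array 186 left out it was 0.0505 and 0.0597. With tumour array 1 left out that of Rpl4 was 0.0531. The adjusted p of Rpl4 was also 0.164 on the blank-subtracted signal, 0.1404 with scaling to the same median and 0.0528 with the authors' values, that of F7 was 0.0560 with scaling to the same median, and that of Rps19 was 0.0840 with the authors' values. With no filter Nsdhl and Rpl4 were at 0.0519 and 0.0515, and with the compared groups alone at 0.0576 and 0.0771. The call on Rpl4 also ended with an intensity trend. Over all alternatives the ranges were 0.00557 to 0.956 for F11, 0.0124 to 0.999 for F7, 0.00551 to 0.999 for Idi1, 0.0101 to 0.379 for Nsdhl, 0.0290 to 0.999 for Rpl4 and 0.00466 to 0.999 for Rps19.

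The 13 genes set beforehand did not pass the test between diets in the main model. Afp was at 5.10 ± 1.13 on normal diet and 6.60 ± 0.954 in high fat diet non-tumour liver (log2 fold change 0.05 ± 0.26, adjusted p 0.950). Gpc3 was at 5.5 ± 0.283 and 12.1 ± 4.28 (0.18 ± 0.14, 0.555, and 0.0479 on the blank-subtracted signal, range 0.0479 to 0.999). Ptgs2 was at 6.2 ± 1.84 and 7.80 ± 0.520 (0.05 ± 0.03, 0.352). Il1b was at 66.7 ± 13.4 and 45.4 ± 16.4 (-0.25 ± 0.16, 0.461). Cxcl1 was at 134 ± 43.8 and 126 ± 49.1 (0.02 ± 0.51, adjusted p 0.988). Cxcl9 was at 81.9 ± 28.4 and 164 ± 87.4 (0.72 ± 0.32, 0.284). Il33 was at 10.9 ± 0.707 and 16.6 ± 2.39 (0.15 ± 0.15, 0.649). Cyp7a1 was at 154 ± 3.46 and 138 ± 28.7 (-0.01 ± 0.17, 0.981). Glul was at 714 ± 4.38 and 899 ± 213 (0.44 ± 0.54, 0.717). Mki67 was at 10.8 ± 1.06 and 16.3 ± 2.41 (0.15 ± 0.07, adjusted p 0.318). Acta2 was at 19.1 ± 0.778 and 79.9 ± 84.8 (0.77 ± 0.62, 0.570). Col1a1 was at 6 and 12.7 ± 2.22 (0.18 ± 0.15, 0.582). Cdkn1a was at 4.75 ± 2.47 and 37.7 ± 9.36 (0.74 ± 0.30, adjusted p 0.230). It was called higher with the authors' values (3.06, adjusted p 0.0101), on the blank-subtracted signal (3.14, 0.01), with the compared groups alone (0.0349) and without tumour array 1 (0.0476, range 0.01 to 0.999).

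Between diets the remaining lists were not called. The adjusted p was 0.186 for aryl hydrocarbon and xenobiotic receptor targets, 0.445 for B and plasma cell, endothelial and periportal genes, 0.659 for bile acid genes and the prostaglandin pathway, 0.550 for cholangiocyte markers, 0.740 for the circadian clock and 0.747 for mature hepatocyte genes. It was 0.903 for muscle and mesothelial markers and the unfolded protein response, 0.237 for neutrophil markers, 0.601 for pancreas and gut markers, 0.468 for red blood cell markers, and 0.669 for sex chromosome genes. It was 0.168 for T and NK cell markers, 0.844 for Wnt and pericentral genes and 0.229 for RAS and MAPK feedback targets. The set test pointed up for B and plasma cell, hepatocyte, unfolded protein response and Wnt lists although their medians were negative, and down for sex chromosome genes although theirs was positive. Red blood cell markers had a median of 0.97 and a mean of 0.75, where camera pointed up and fry down. Of these 8 markers 1 fell, while adjusted over the list alone 4 rose and 2 fell. Xenobiotic receptor targets passed with the authors' values (0.0469, range 0.0469 to 0.731). Immediate early genes (0.170) passed with the authors' values (0.0213) and without non-tumour array 117 (0.0426, range 0.0213 to 0.731). The interferon response (0.229) passed with scaling to the same median (0.0442) and without normal diet array 117 (0.00805, range 0.00805 to 0.992). The senescence list (0.0852) was called higher with the authors' values (0.000378), on the blank-subtracted signal (0.00697) and with the compared groups alone (0.0208). It also passed without tumour array 186 (0.0392) or non-tumour array 1 (0.0146, range 0.000378 to 0.584). The oxidative phosphorylation list (median -0.04, adjusted p 0.802) was called lower with the authors' values (median -0.31, adjusted p 0.00160) and higher with scaling to the same median (median 0.12, adjusted p 0.00737, range 0.00160 to 0.939).

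Between diets 645 of 16800 genes changed (304 higher, 341 lower), 67 and 35 of them over 2-fold, and 16 of 38 lists were called (12 higher, 4 lower). With an estimated correlation 0 lists were called. In 7399 genes (44.0%, where chance gives 20%) the groups' arrays did not overlap. The count was 132 without normal diet array 117, 103 without normal diet array 120, and 254, 256 and 373 without non-tumour arrays 117, 186 and 1, and 1403 with scaling to the same median. Of those 1403 genes 77.3% were higher, and 60.3% of 748 on the blank-subtracted signal, against 47.1%. With the local background of each spot 3 genes changed (807 before adjustment in limma) and 10 lists were called, and 94.0% of the 645 genes kept their direction. Cell cycle (adjusted p 0.145), cholesterol synthesis (0.0834), complement (0.145), glycolysis (0.567), NRF2 (0.0952) and ribosomal (0.834) lists lost their calls there, as did 40 of the 42 named genes called between diets, Hsd3b5 with a reversed sign among them. By fry 12 lists were called, with cell cycle (0.148), cholesterol synthesis (0.0949), glycolysis (0.0991) and ribosomal genes (0.0949) not among them.

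**Figure D2:**
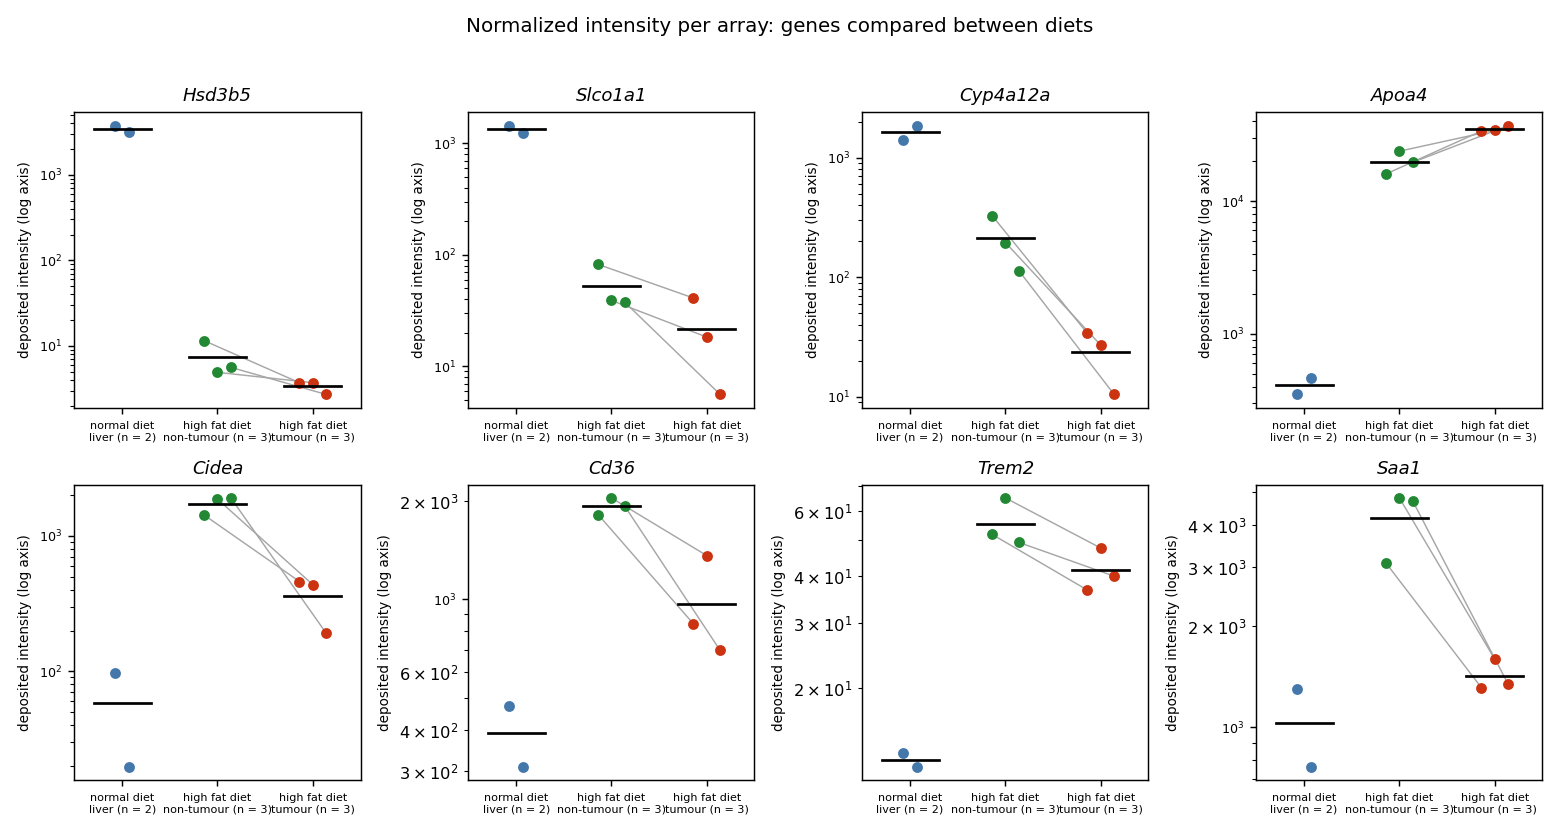
Deposited normalized intensity of 8 genes on a log axis, with arrays, means and lines drawn as for the tumour genes. Hsd3b5, Slco1a1 and Cyp4a12a were lower, and Apoa4, Cidea, Cd36, Trem2 and Saa1 higher, in non-tumour liver of mice on high fat diet than in liver of mice on normal diet, where Hsd3b5 reversed to 0.43 with the local background of each spot (adjusted p 0.196, range 2.4e-09 to 0.196).

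Tumours (n = 3) were also set against liver of mice on normal diet (n = 2), where Ly6d rose and Hsd3b5 fell most among the named genes. Here too the scanner gain slope and the blank level separated the normal diet arrays from the others, so a batch cannot be told apart from the difference between tumour and normal diet liver. Ly6d was at 25.4 ± 1.98 in normal diet liver and 7663 ± 2183 in tumours (log2 fold change 7.03 ± 0.23, adjusted p 5.1e-05). Apoa4 was at 408 ± 83.3 and 34879 ± 1795 (6.62 ± 0.24, adjusted p 5.1e-05). Akr1c18 was at 19 ± 0.566 and 4011 ± 1030 (6.19 ± 0.37, adjusted p 0.000250). Lcn2 was at 43.2 ± 7.42 and 4987 ± 1783 (6.04 ± 0.28, adjusted p 0.000103). Tspan8 was at 17.6 ± 8.27 and 3502 ± 1378 (5.98 ± 0.39, adjusted p 0.000295). Igfbp1 was at 131 ± 154 and 6476 ± 2668 (5.82 ± 0.63, adjusted p 0.00149). Hsd3b5 fell to 3.37 ± 0.577 (-5.85 ± 0.08, adjusted p 2.1e-06), and the Fshb probe from 7960 ± 842 to 158 ± 134 (-5.15 ± 0.72, adjusted p 0.00354). The cytochrome P450 gene Cyp2c54 fell from 4874 ± 611 to 136 ± 110 (-4.63 ± 0.65, adjusted p 0.00354) and Cyp2c50 from 3958 ± 284 to 135 ± 116 (-4.35 ± 0.68, adjusted p 0.00508). Cyp1a2 fell from 4291 ± 156 to 128 ± 95.2 (-4.38 ± 0.52, adjusted p 0.00200) and the sulfotransferase gene Sult2a8 from 5054 ± 428 to 174 ± 147 (-4.40 ± 0.63, adjusted p 0.00364). With the local background of each spot the fall of Hsd3b5 reversed to 0.41 (adjusted p 0.0476, in a range of 2.0e-09 to 0.0476).

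Oncofetal markers rose in 23 of 29 cases against normal diet liver, 24 adjusted over the list alone (adjusted p = 1.1e-15, and adjusted p = 0.0502 with an estimated correlation). Afp was at 5.10 ± 1.13 and 864 ± 390 (4.29 ± 0.26, adjusted p 0.000248). Gpc3 was at 5.5 ± 0.283 and 729 ± 91.3 (4.16 ± 0.14, adjusted p 5.1e-05). Male-biased genes fell in 14 of 18 cases and rose in 1, 15 and 1 adjusted over the list alone (adjusted p = 1.7e-07, and adjusted p = 0.181 with an estimated correlation). Oxidative phosphorylation genes fell in 25 of 32, 26 adjusted over the list alone (adjusted p = 5.8e-10, and adjusted p = 0.0502 with an estimated correlation). The unfolded protein response list rose in 17 of 26 cases, 20 adjusted over the list alone (adjusted p = 9.9e-10, and adjusted p = 0.0502 with an estimated correlation). Cell cycle genes rose in 19 of 32 and fell in 1, 22 and 1 adjusted over the list alone (adjusted p = 3.4e-07, and adjusted p = 0.417 with an estimated correlation). Senescence genes rose in 13 of 28 and fell in 2, 16 and 3 adjusted over the list alone (adjusted p = 0.000181, and adjusted p = 0.386 with an estimated correlation). Ribosomal protein genes rose in 11 of 26 cases and fell in 1, 14 and 1 adjusted over the list alone, at a list median of 0.27 that flipped to -0.16 with the authors' values (adjusted p = 0.000865, adjusted p = 0.417 with an estimated correlation, 0.556 with the authors' values, range 7.2e-05 to 0.556).

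Fat storage, inflammation and matrix lists were called higher in tumours than in normal diet liver as well, with estimated-correlation values far above 0.05. Cholesterol synthesis genes rose in 12 of 19 cases, 13 adjusted over the list alone (adjusted p = 2.7e-05, and adjusted p = 0.392 with an estimated correlation). Stellate genes rose in 10 of 32 cases and fell in 1, 14 and 1 adjusted over the list alone (adjusted p = 4.9e-05, and adjusted p = 0.396 with an estimated correlation). Acute phase genes rose in 13 of 29 cases and fell in 6, 16 and 6 adjusted over the list alone (adjusted p = 0.00152, and adjusted p = 0.396 with an estimated correlation). Lipid droplet genes rose in 11 of 27 cases and fell in 2, 13 and 2 adjusted over the list alone (adjusted p = 0.00248, and adjusted p = 0.392 with an estimated correlation). Macrophage markers rose in 13 of 29 cases and fell in 5, 15 and 6 adjusted over the list alone (adjusted p = 0.00479, and adjusted p = 0.438 with an estimated correlation). Bile acid genes fell in 18 of 29 cases and rose in 2, 19 and 2 adjusted over the list alone (adjusted p = 0.000100, and adjusted p = 0.396 with an estimated correlation). Wnt and pericentral genes fell in 15 of 22 cases and rose in 1, 16 and 2 adjusted over the list alone (adjusted p = 0.000281, and adjusted p = 0.417 with an estimated correlation).

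Other lists were also called in tumours against normal diet liver. MAPK targets (8 of 20 rose, adjusted p = 0.00282, adjusted p = 0.426 with an estimated correlation) and immediate early genes (6 of 20 rose, adjusted p = 0.00712, adjusted p = 0.417 with an estimated correlation) were higher, with 8 and 7 rising adjusted over the list alone. Endothelial markers were higher (7 of 22 rose and 1 fell, the same adjusted over the list alone, adjusted p = 0.0118, adjusted p = 0.417 with an estimated correlation, 0.0644 without tumour array 186, range 0.000768 to 0.417). So were glycolysis genes (8 of 22 rose and 2 fell, 9 and 2 adjusted over the list alone, adjusted p = 0.0210, adjusted p = 0.460 with an estimated correlation). Their call ended without normal diet array 117 (0.0543) or tumour array 1 (0.0824) and with the authors' values (0.102, range 0.00688 to 0.460). Cholangiocyte markers rose in 4 of 16 cases, 4 adjusted over the list alone (adjusted p = 0.0364, adjusted p = 0.417 with an estimated correlation, 0.0601 without normal diet array 117 and 0.117 without tumour array 117, range 0.00956 to 0.417). Female-biased genes rose in 10 of 20 cases and fell in 5, 10 and 6 adjusted over the list alone (adjusted p = 0.0453, adjusted p = 0.386 with an estimated correlation, 0.0858 and 0.0845 without tumour arrays 117 and 186, range 0.000192 to 0.386). Mature hepatocyte genes fell in 13 of 24 cases and rose in 2, 16 and 3 adjusted over the list alone (adjusted p = 0.0132, adjusted p = 0.528 with an estimated correlation, 0.0600 without normal diet array 117, range 0.000141 to 0.528). Periportal genes fell in 11 of 20 cases and rose in 5, 13 and 5 adjusted over the list alone (adjusted p = 0.0410, adjusted p = 0.456 with an estimated correlation). The periportal call ended with scaling to the same median (0.0876) and without normal diet array 120 (0.0823) or non-tumour array 117 (0.0519), and with the compared groups alone (0.0627), in a range of 0.00719 to 0.456. Fatty acid synthesis genes (adjusted p 0.0785) and the interferon response (0.158) were not called, but passed without normal diet array 117 (0.0434 and 0.0168, ranges 0.00127 to 0.417 and 0.0168 to 0.760) and with scaling to the same median (0.0304 and 0.0170). Aryl hydrocarbon and xenobiotic receptor targets were not called (8 of 21 fell and 3 rose, 0.366), nor were adipose (0.505), B and plasma cell (0.373), circadian (0.496), complement (0.373), muscle (0.524), neutrophil (0.402), NRF2 (0.923) and pancreas (0.383) lists. PPAR alpha (0.344), prostaglandin (0.804), red blood cell (0.691), sex chromosome (0.495) and T and NK cell (0.428) lists were not called either. With the authors' values complement (0.00866, range 0.00417 to 0.666) and PPAR alpha lists (0.0181, range 0.0181 to 0.708) were called lower.

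Of the genes set beforehand, several passed between tumours and normal diet liver. Cyp7a1 fell (154 ± 3.46 to 25.4 ± 12.4, -1.37 ± 0.17, adjusted p 0.00235), Il33 rose (10.9 ± 0.707 to 76.6 ± 24.2, 1.15 ± 0.15, adjusted p 0.00269) and so did Mki67 (10.8 ± 1.06 to 32.4 ± 8.30, 0.47 ± 0.07, adjusted p 0.00431). Cdkn1a rose (4.75 ± 2.47 to 120 ± 68.1, 1.72 ± 0.30, adjusted p 0.00723, and 0.0522 without normal diet array 120, range 0.000187 to 0.270). So did Cxcl1 (134 ± 43.8 to 741 ± 479, 2.26 ± 0.51, adjusted p 0.0188, 0.0766 and 0.116 without normal diet array 117 and 120, 0.0533 with the compared groups alone, range 0.00347 to 0.734). Cxcl9 rose (81.9 ± 28.4 to 241 ± 20.8, 1.40 ± 0.32, adjusted p 0.0216), a call that ended without normal diet array 117 (0.0727) or 120 (0.133) or tumour array 117 (0.0560) or 1 (0.0519), in a range of 0.00392 to 0.276. Glul fell (714 ± 4.38 to 155 ± 136, -1.83 ± 0.54, adjusted p 0.0475), a call that ended without normal diet array 117 (0.176) or 120 (0.184), non-tumour array 117 (0.0723), 186 (0.0687) or 1 (0.0751), or tumour array 117 (0.114) or 1 (0.0751). It also ended with no filter (0.0614) and with the compared groups alone (0.110). Its range was 0.00370 to 0.555. Ptgs2 was at 6.2 ± 1.84 and 8.47 ± 1.61 (0.07 ± 0.03, adjusted p 0.121). Il1b was at 66.7 ± 13.4 and 54.2 ± 8.16 (-0.08 ± 0.16, 0.752). Acta2 was at 19.1 ± 0.778 and 176 ± 120 (1.75 ± 0.62, adjusted p 0.0831, range 0.0206 to 0.261). Col1a1 was at 6 and 26.3 ± 17.1 (0.47 ± 0.15, adjusted p 0.0676, range 0.00530 to 0.521). Both passed with the authors' values (0.0206 and 0.00730), on the blank-subtracted signal (0.0228 and 0.00530) and with an intensity trend (0.0301 and 0.0232). Acta2 also passed without non-tumour array 117 (0.0472), and Col1a1 without tumour array 186 (0.00605) or 1 (0.0461).

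Between tumours and normal diet liver 4673 of 16800 genes changed (2161 higher, 2512 lower), 399 and 341 of them over 2-fold, and 22 of 38 lists were called (16 higher, 6 lower), where 0 were called with an estimated correlation. In 9622 genes (57.3%, where chance gives 20%) the groups' arrays did not overlap. The count was 2315 without normal diet array 117 and 2476 without normal diet array 120, and with the authors' values 32.0% of 5108 changed genes were higher against 46.2%. With scaling to the same median 6861 genes changed (2672 higher, 4189 lower, so 38.9% higher). The authors' values set the median of all genes at -0.20 in this comparison and -0.12 between diets. With the local background of each spot 224 genes changed (135 higher, 89 lower, so 60.3% higher) and 19 lists were called, and 91.9% of the 4673 genes kept their direction. Cholangiocyte (adjusted p 0.0749), glycolysis (0.427), MAPK (0.197) and ribosomal (0.179) lists lost their calls there. So did 9 of the 21 named genes called here, Hsd3b5 with a reversed sign among them. Fatty acid synthesis was called higher (0.0252). By fry 30 lists were called, the 22 lists and a further 8: adipose (0.0266), B and plasma cell (0.0221), fatty acid synthesis (0.00127), muscle (0.0158), pancreas (0.0378), complement (0.00417, lower), red blood cell (0.00255, lower) and sex chromosome genes (0.0433, lower). The red blood cell list had a median of 0.79 and a mean of 0.34, positive although both set tests pointed down and 3 of 8 members fell. Adipose and B and plasma cell lists had medians of -0.01 and means of 0.14 and 0.70 where both tests pointed up.

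**Figure D3:**
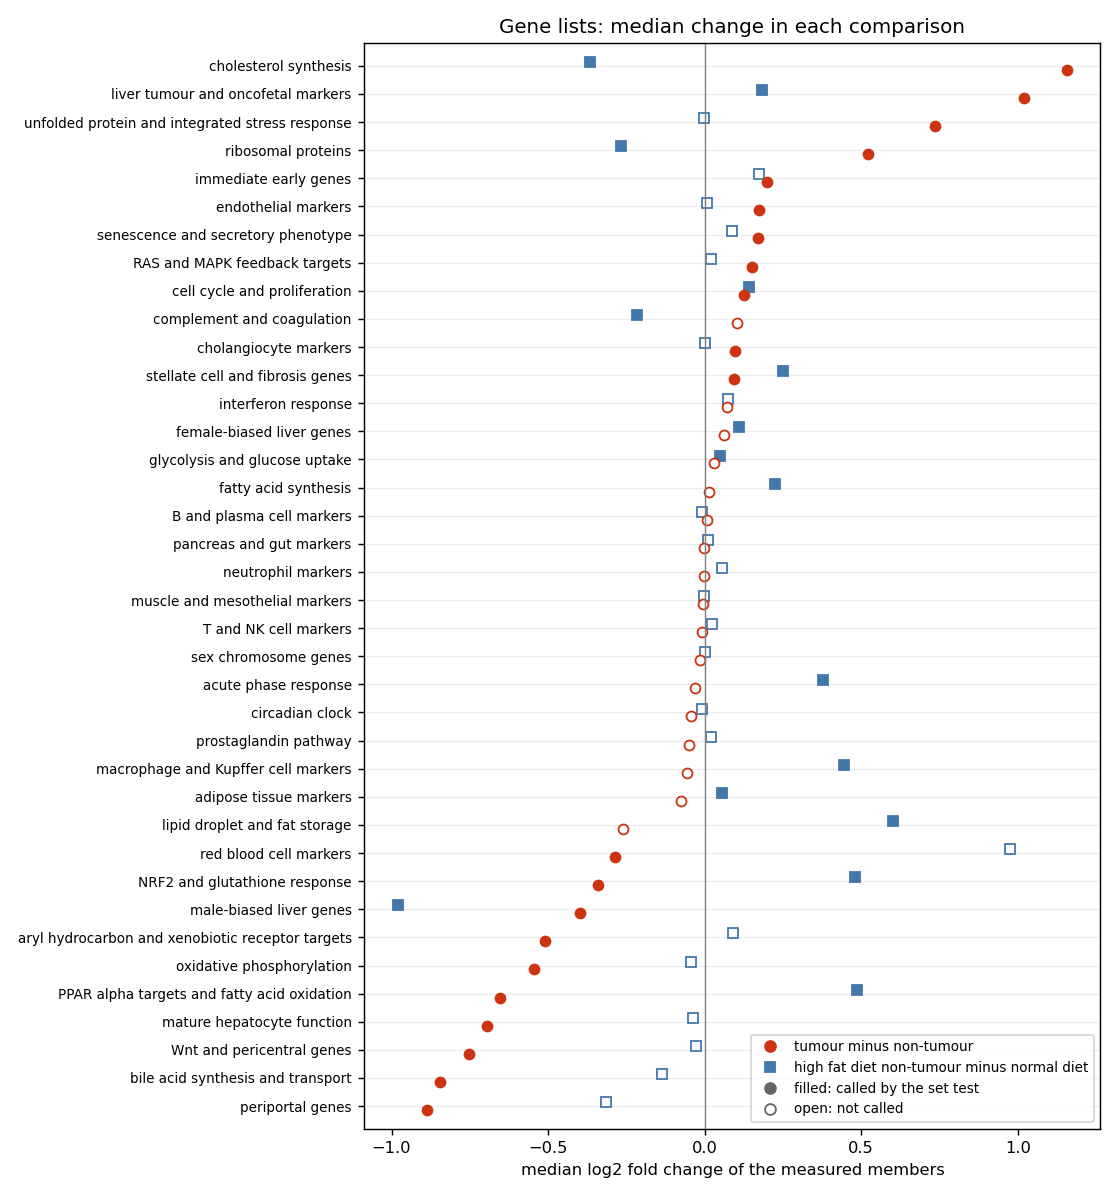
Median log2 fold change of the measured members of each of 38 gene lists, for tumour minus non-tumour tissue of high fat diet livers (red circles) and high fat diet non-tumour minus normal diet liver (blue squares). Filled symbols mark lists called by the set test with a preset correlation of 0.01. Between diets the oxidative phosphorylation list, not called here, flips from -0.04 to 0.12 with scaling to the same median, and between tumour and non-tumour tissue the complement and coagulation list, not called either, flips from 0.10 to -0.10 with that scaling.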

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

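Probes that the array table leaves without a gene name lie outside the gene-level comparisons, and some of them passed the same test. Of 2276 such probes tested, 478 passed between tumour and non-tumour tissue (242 higher, 236 lower), 78 between diets (44 higher, 34 lower) and 537 between tumours and normal diet liver (258 higher, 279 lower). The probe M200000114 was at 946 ± 316 in non-tumour tissue and 9917 ± 3252 in tumours (log2 fold change 3.66 ± 0.33), and M400002420 was at 19.2 ± 10.6 on normal diet and 693 ± 167 in high fat diet non-tumour liver (3.45 ± 0.20). Their genes were not looked up here.

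The tests on sex, batch and hepatocyte share below were chosen only after the results were seen. Male-biased liver genes had a median log2 change of -0.98 between diets, where random lists matched on signal reached -0.09 at their 2.5th percentile. Quantile normalization had already evened out shifts shared by genes of like signal, so those lists had to lie near no change. A scanner or scaling effect that depends on signal intensity therefore cannot be judged from them. Mice of different sex in the diet groups are argued against, since the Y-linked gene Eif2s3y differed by 0.0014 (SE 0.12; 261 ± 31.2 and 233 ± 31.8) and Xist by 0.01. An array or scan batch that coincides with diet cannot be told apart from diet: the slope between readings at different scanner gains was 0.216 on normal diet arrays and 0.232 to 0.235 on high fat diet arrays, a gap of 0.016, and blank spots were brighter on the latter. Diet may account for the fall, and this stays open.

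Mature hepatocyte, fatty acid oxidation and bile acid genes together (80 genes) had a median of -0.7 in tumours against non-tumour tissue. Random lists matched on signal reached -0.13 at their 2.5th percentile. As above, quantile normalization holds such lists near no change, so they cannot decide on a scanner or scaling effect that depends on signal intensity. A lower share of hepatocytes in the tumour samples would likely lower complement and coagulation genes alike. Yet their median was 0.10 (9 rose and 5 fell), against -0.70 for mature hepatocyte genes. The 95% bounds of -0.13 and 0.44 on that 0.10 come from resampling the genes of the list, as do the bounds below. They measure the spread among genes, not among the 3 mice. A lower share might also raise markers of other cell types, though not necessarily alike. Endothelial, stellate and cholangiocyte lists were called higher, which goes with it. Their medians were 0.17 (95% bounds 0.02 and 0.34), 0.09 (0.006 and 0.51) and 0.10 (-0.02 and 0.36). The cholangiocyte list shares Tspan8 with the oncofetal list. Red blood cell markers were called lower (-0.29, bounds -0.66 and -0.18). Those 4 calls were lost with an estimated correlation (adjusted p = 0.519, 0.560, 0.519 and 0.519 with an estimated correlation). Macrophage, T and NK cell, B and plasma cell and neutrophil lists were not called, at medians of -0.056, -0.0079, 0.0059 and -0.0025. Markers of other cells therefore leave the question open. With the authors' values and with scaling to the same median the complement median was -0.14 and -0.10. A loss of hepatocytes masked by a rise of these secreted factors was not tested, and a change within tumour cells stays open as a hypothesis.

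Far fewer genes passed when the local background was subtracted. The local background reading followed the signal of its own spot on every array (rank correlation 0.913 to 0.959). Whether this adds noise to the difference, and so accounts for the fewer calls, could not be told. The standard deviation between arrays of a group rose by a ratio of 1.32, from 0.065 to 0.086. That ratio lay between the limits set before this test for and against the explanation. Of the genes called between tumour and non-tumour tissue 91.7% kept their direction. Whether the blank spots miss a local haze stays open.

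Of the 10 ways to split the 6 high fat diet arrays into 3 and 3, only 1, the real split, gave 4267 genes, and the highest other split gave 0 in limma, with 165 to 1025 genes at unadjusted p below 0.05 in the others against 6219. The highest among the 4 splits that part all 3 pairs, the real one set aside, was 0 as well. Every other split puts tumour and non-tumour arrays in the same group, so a difference between the tissues enters the spread of its fit and lowers its count. With 10 splits a share under 0.05 could not be reached.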

How the results depend on the processing

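Local background in normexp, added after seeing the data, gave 136, 3 and 224 genes for tumour against non-tumour tissue, non-tumour liver between diets and tumours against normal diet, where the blank spots gave 4267, 645 and 4673. It gave 10 lists between diets against 16. It also reversed Hsd3b5 to 0.43 between diets and 0.41 in tumours against normal diet, where the local reading was as bright as the spot. Scaling to the same median gave 1403 genes between diets, and the cause was not tested. Camera with an estimated correlation called 2 lists (4 at unadjusted p below 0.05) in the tumour against non-tumour comparison and 0 in the others (7 and 4), where fry called 23, 12 and 30 and the preset correlation 21, 16 and 22. Leaving out 1 array gave 3105 to 4172, 103 to 780 and 2315 to 4412 genes and 17 to 21, 15 to 17 and 20 to 22 lists, with fewer arrays in each fit.

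All other settings stayed within 1.5 times these counts. Mouse as a block gave 3485 genes and 19 lists, ended the calls of 8 named genes and 2 lists between tumour and non-tumour tissue and changed no other named gene or list call. With mouse as a random block (consensus correlation 0.199) 5081 genes changed. Over 145 named genes and comparisons 2595 alternative values were computed, of which 2295 stayed on their side of the threshold in direction and call, 269 were weaker, 15 stronger, 14 moved and 2 reversed. A fit with scan or slide date as a block was not run, since the files used hold no such date. Signal over background limits the dim genes: with an offset of 50 a gene near the blank level shows a smaller log2 change than its deposited intensities do.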

Other observations

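The genes below were chosen after their values were seen. A set of genes moved 1 way from normal diet liver to high fat diet non-tumour liver and the other way from there to tumours. At the first of these steps an array or scan batch cannot be told apart from diet. The monoacylglycerol acyltransferase gene Mogat1 was at 22.5 on normal diet, 162 in high fat diet non-tumour liver and 22.1 in tumours (log2 fold changes 1.62 ± 0.12 and -1.61 ± 0.11), the carnitine acetyltransferase gene Crat at 108, 326 and 119, the small heat shock protein gene Hspb1 at 387, 1304 and 307, and the serum amyloid gene Saa3 at 119, 283 and 107. In the other order Atf4, a transcription factor of the integrated stress response, was at 854, 341 and 633 and the sterol carrier gene Stard4 at 224, 88.3 and 183. Among acute phase genes 5 rose and then fell and 4 rose at both steps, among lipid droplet genes 4 and 2, among NRF2 genes 3 and 1, and among PPAR alpha genes 4 and 0. Female-biased and oncofetal lists each had 4 genes that rose at both steps, the male-biased list had 3 that fell at both, and 3 cholesterol synthesis genes fell and then rose. These counts per list were not tested.

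Other genes moved the same way at both steps. The apolipoprotein gene Apoc2 was at 2180, 6061 and 16521, and the metallothionein genes Mt1 and Mt2 were at 349, 940 and 3598 and at 176, 607 and 2552. The carboxylesterase gene Ces2a was at 5575, 1027 and 305, the acetyltransferase gene Nat8 at 789, 130 and 19.4, and the transsulfuration gene Cth at 3652, 1510 and 393. These levels are means of 2, 3 and 3 arrays, and all of these genes passed the test at both steps, though their calls were not repeated under the alternatives. Genes that rose at both steps numbered 72 (36.3 from the product of the counts) and genes that fell at both 94 (45.9), while 131 rose and then fell (40.9) and 72 fell and then rose (40.8). Both steps share the non-tumour arrays, which enter them with opposite sign. Simulated data without any effect gave a correlation of -0.453 against 0.076 and a covariance of -0.0057 against 0.0079. Noise of the shared arrays thus favours opposite moves and works against moves in the same direction. The simulated overlap of 0 cannot show what sharing adds among genes that do change. Both steps also share the estimate of the spread, and the 3 shared arrays were not split further. How much of the excess comes from sharing is therefore not known, and the excess is not read as a shared effect.

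Of 1102 spots without a probe, 5 (0.454%) lay above the blank mean plus 2 standard deviations on all 8 arrays. The brightest had a mean scanner signal of 25.5, before any correction. On that scale the blank means of the arrays were 18.4 to 22.7 and their median probes 30.9 to 45.1.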
